A study of Danio rerio with 36 samples.

How the data were processed

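RNA was measured in 36 libraries of pooled zebrafish larval heads, collected in front of the swim bladder 10 days after fertilization from a mixed wild-type line, in 2 experiments with the same 3 groups. Per the labels' protocols, RNA of experiment 1 was isolated by a contract laboratory, ribosomal RNA was depleted and stranded libraries were read as pairs, while RNA of experiment 2 was extracted in the study's own laboratory and selected for polyA tails. Per the submitters' processing notes, reads were handled with bcl2fastq and Partek 8.0.19.0428 and aligned with STAR 2.5.3a to GRCz11. The gene annotation, and whether counting used the strand, are not given in the sources used here, so genes that overlap on either strand or have close copies could share reads, and their values are uncertain.

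The values are deposited estimated counts per gene, not normalized, with 24860 genes in experiment 1 and 25077 in experiment 2 and 24023 symbols in both. They need not be whole, since 9.44% and 17.3% of values lay more than 0.01 from a whole number, and they were rounded to whole numbers before testing. The design had assumed whole counts, and its test was kept. No column lacked a sample and no gene lacked a name (0 in either table). The smallest sum over libraries was 10 in experiment 1, and 4 genes were at 0 in every library of experiment 2.

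Genes were tested with edgeR 4.0.16 in R 4.3.3, by a quasi-likelihood fit with a mean per group over the 18 libraries of each experiment, TMM scaling and edgeR's filter on low counts, which left 19727 and 20169 genes. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, two-sided, and the SE was the absolute log2 fold change divided by the square root of the F statistic. Differences between experiments were tested as interactions in one edgeR fit over 36 libraries and 21208 genes. CPM values are after TMM scaling. Low groups were compared by summed counts with a 95% exact interval, or with 3 counts over the group as the floor where the sum was 0. Genes called against both colonized groups share the axenic libraries. The overlap of independent calls, a split of the axenic libraries and 10 simulations with no changed gene were computed beside them.

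Before the data were examined, the groups, tests, 48 gene lists, the rule for named genes and the alternatives were fixed. The lists held 2176 symbols, of which 1984 matched the tables, and were tested with camera in limma 3.58.1 at a preset correlation of 0.01 with at least 5 tested members, with Benjamini-Hochberg adjustment over the lists of a comparison. Named genes had a proper symbol and a mean of at least 1 CPM. They were the 8 genes in each direction with the largest smaller fold change among those called against both colonized groups, the 5 in each direction with the largest fold change per comparison, the 8 in each direction called in both experiments, and per list that passed or had 3 or more called members the 4 with the smallest adjusted p. Last ranks of the per-comparison and per-list kinds were left out for length, and any other gene is said to be named after its values were seen.

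The procedure was tested on simulated counts with 200 changed genes. At log2 fold changes of 0.5, 1 and 2 it recovered 35.8%, 85.1% and 100% in axenic against conventional heads of experiment 1, over 19503 genes, and 29.9%, 83.6% and 100% against re-colonized heads. In experiment 2 (19716 genes) it recovered 0%, 20% and 63.6%, and 0%, 26.2% and 66.7%, so most changes of up to 2-fold could be missed. The interaction recovered 0%, 11.9% and 69.7% over 18767 genes. With genes drawn independently, 12 of 12 shifted lists passed in either experiment and 0 of 16 and 0 of 15 unshifted ones. Correlated genes were not tested.

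No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom being 5.55 in experiment 1 and 29.5 in experiment 2. Alternatives fixed in advance were DESeq2 1.42.0, limma voom with quality weights, DESeq2's size factors in edgeR, no filter, a filter at a mean of 1 CPM, a fit of the 2 groups compared alone, the replicate number or letter as a block, an estimated correlation, fry, and leaving out each library. Chosen after seeing the data was leaving out structural RNAs, re-colonized 1 and 7 of experiment 2, or axenic 7 for counts across experiments. Other splits of the libraries into groups of the same sizes were drawn 100 times (50 for differences between experiments). The share of brain in each pool was not measured, and behaviour was not analysed here.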

Results

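Messenger and other transcripts were counted in 36 libraries, each from pooled heads of zebrafish larvae 10 days after fertilization, in 2 experiments of 18 libraries. Axenic larvae were kept free of microbes, conventional larvae carried a normal microbial community, and re-colonized larvae were made axenic in the same way and then given microbes on day 1, which makes them the control for the derivation. The study set out to find molecular changes that go with the hyperactive swimming of axenic larvae. Experiment 1 held 6 axenic (A, C, D, F, G, H), 6 re-colonized (B, D, E, F, G, H) and 6 conventional libraries (A, B, C, F, G, H) from total RNA depleted of ribosomal RNA, and experiment 2 held 4 axenic (1, 3, 4, 7), 7 re-colonized and 7 conventional libraries from polyA-selected RNA. Total counts per library were 13402268 to 15017642 (axenic), 11716742 to 13100744 (re-colonized) and 11876631 to 14442806 (conventional) in experiment 1. In experiment 2 they were 16059421 to 24856654, 18354290 to 23554845 and 15148058 to 25760592. Nothing in the labels says that the pools came from separate spawns, so p-values measure the spread between these pools only, and intervals and floors cover counting error only.

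In experiment 1, 2 structural RNAs, the 7SL RNA of the signal recognition particle (RF00017, 32.6% of counts) and the 7SK RNA (rn7sk, 8.8%), took 39.9% ± 3.97 of axenic, 41.6% ± 2.96 of re-colonized and 42.8% ± 2.03 of conventional counts (SD, n = 6 each). The biological coefficient of variation was 16.5% in experiment 1 and 35.5% in experiment 2, so the same fold change was harder to call in the latter. Library names of experiment 1 carry L6 in axenic and re-colonized and L7 in conventional libraries, a mark whose meaning the labels do not give and which cannot be told apart from the group in comparisons with conventional heads. On the first principal component of experiment 1, which held 28.65% of the variance, the 6 axenic libraries lay between -54.1 and -22.5 and the 12 colonized libraries between 12.6 and 35.5. In experiment 2 the first component (23.64%) ran across all 3 groups, and the second (15.07%) placed the 4 axenic libraries between 29 and 93.6 and the 14 colonized ones between -43 and 16.5. Re-colonized 1 and 7 of experiment 2 stood apart on the first component (-84.8 and -61.3) and had TMM scaling factors of 1.549 and 1.376, above the 0.7694 to 1.208 of the other libraries. Values that follow a gene name or "rose by" and "fell by" are log2 fold changes with their SE from edgeR's quasi-likelihood test, and adjusted p is by Benjamini-Hochberg. Head pools could also hold eye, skin, muscle, skeleton, blood and tissue from behind the head, and marker lists for these were among the 48 gene lists fixed before the data were examined.

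**Figure D1:**
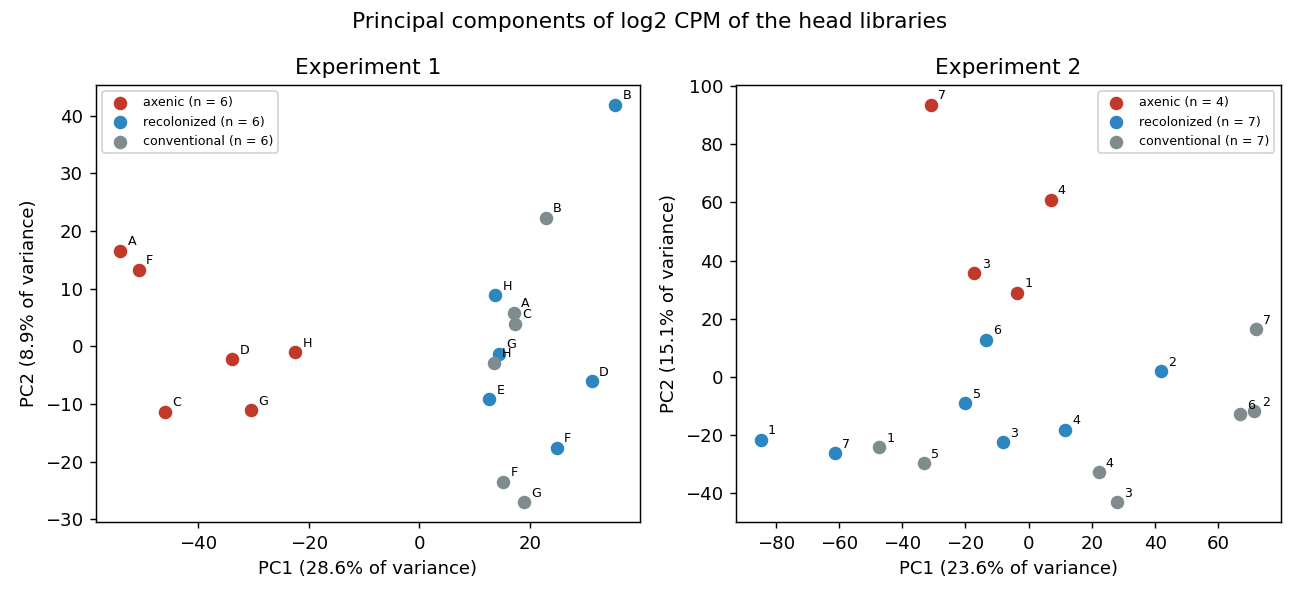
Principal components 1 and 2 of log2 CPM for the 18 libraries of each experiment, with the percent of variance on each axis, 1 point per library and a colour per group. Axenic libraries lie apart from colonized ones on the first component in experiment 1 (-54.1 to -22.5 against 12.6 to 35.5) and on the second in experiment 2 (29 to 93.6 against -43 to 16.5).

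Comparing axenic with conventional heads asks which transcripts differ when microbes are absent. In experiment 1, axenic heads held more transcript of skeletal, matrix, muscle, photoreceptor and fatty acid oxidation genes and less of inflammatory and leukocyte genes. apobb.2, an apolipoprotein B gene (chromosome 20, 53439665 to 53470253, GRCz11), rose by 4.76 (SE 0.65, edgeR adjusted p = 1.45e-05), from 0.471 ± 0.359 CPM in conventional heads to 12.8 ± 12.5 CPM in axenic heads (SD, n = 6 each). It was higher in 6 of 6 axenic libraries than the conventional mean. enam, the gene of an enamel matrix protein (chromosome 1, 43901966 to 43905264), rose by 3.04 (SE 0.32, edgeR adjusted p = 4.13e-07), from 1.38 ± 0.368 CPM in conventional heads to 11.5 ± 6.74 CPM in axenic heads (SD, n = 6 each). Its value was higher in 6 of 6 axenic libraries than the conventional mean. irg1l, on chromosome 14, 11427052 to 11430611, a paralog of acod1, fell by 4.0 (SE 0.58, edgeR adjusted p = 3e-05), from 31.3 ± 25.3 CPM in conventional heads to 1.95 ± 0.488 CPM in axenic heads (SD, n = 6 each). It was lower in 6 of 6 axenic libraries than the conventional mean. acod1, the gene of the enzyme that makes itaconate in macrophages, gave 3 counts in the 6 axenic libraries together against 138 in the 6 conventional ones, 49.9-fold lower by CPM (95% exact interval 16.7 to 245, edgeR adjusted p = 6.8e-06). apobb.2, irg1l, acod1 and the opsin, keratin, granulin and collagen X genes have close copies in the genome between which the counting could split reads, so their values are uncertain.

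Rises against both colonized groups also included cyp51, lanosterol demethylase (2.8 ± 0.41), klf11b, a Krüppel-like transcription factor (2.54 ± 0.21), ACTC1, a cardiac actin (2.54 ± 0.37) and krtt1c19e, a keratin (2.86 ± 0.24), with edgeR adjusted p = 8.23e-09 to 3.62e-05. Falls included nos2a, inducible nitric oxide synthase (-4.68 ± 1.07), mxf, an antiviral Mx GTPase (-3.64 ± 0.70), arf4b (-3.33 ± 0.44), slc2a6, a hexose transporter (-2.87 ± 0.43), zc3h12a, an RNase that removes inflammatory mRNAs (-2.39 ± 0.30) and nox1, an NADPH oxidase (-2.21 ± 0.24), with edgeR adjusted p = 5.3e-07 to 0.0035. clca1, a secreted chloride channel accessory protein, fell by 3.65 (SE 0.33, edgeR adjusted p = 4.46e-08). By edgeR's quasi-likelihood test, 3077 of 19727 genes passed, 1753 higher and 1324 lower in axenic heads, of which 470 and 289 differed by more than 2-fold. Of 48 gene lists, 35 passed camera at a preset correlation of 0.01, 26 upward and 9 downward, 15 passed with an estimated correlation and 33 by fry, which tests for movement in one direction and does not compare a list with other genes. Median, mean and test had the same sign in every list that passed here and in the other comparisons. With limma voom, nos2a did not pass (adjusted p = 0.212).

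Of 56 cartilage and bone genes, 33 rose, 2 fell and 21 did not pass (37 and 5 adjusted over the list alone). Their median was 0.90 (camera adjusted p = 4.91e-39, adjusted p = 0.00258 with an estimated correlation). They included col9a3, a cartilage collagen (2.31 ± 0.16), col11a1a, another (1.95 ± 0.13), col11a2, a collagen of cartilage fibrils (2.45 ± 0.18), col10a1a, the collagen of hypertrophic cartilage (2.43 ± 0.21) and ifitm5, a bone-forming cell protein (2.73 ± 0.48), with edgeR adjusted p = 1.24e-09 to 0.000268, while acp5a, an acid phosphatase of osteoclasts and macrophages, fell by 1.77 (SE 0.27, edgeR adjusted p = 5.26e-05). Matrix and fibroblast genes rose in 42 of 64 cases and fell in 1, and 21 did not pass (46 and 1 adjusted over the list alone). The median was 0.79 (camera adjusted p = 8.2e-39, adjusted p = 0.0112 with an estimated correlation). col1a2 and col5a1, fibrillar collagens, were at 1.65 ± 0.16 and 1.22 ± 0.12 (edgeR adjusted p = 9.89e-08 and 2.28e-07). 59 of 87 skeletal muscle genes rose, 1 fell and 27 did not pass (67 and 1 adjusted over the list alone). Their median was 0.56 (camera adjusted p = 2.83e-37, adjusted p = 0.0112 with an estimated correlation). pvalb4, a muscle parvalbumin, rose by 1.23 (SE 0.12, edgeR adjusted p = 1.87e-07). Of 49 cell cycle genes, 31 rose, 0 fell and 18 did not pass (43 and 0 adjusted over the list alone). The median was 1.23 (camera adjusted p = 1.93e-18, adjusted p = 0.0937 with an estimated correlation). mcm5, a DNA helicase subunit, rose by 1.84 (SE 0.26, edgeR adjusted p = 2.87e-05), and uhrf1, a cofactor of DNA methylation, rose by 1.46 (SE 0.20, edgeR adjusted p = 1.42e-05).

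Phototransduction genes rose in 33 of 47 cases and fell in 1, and 13 did not pass (37 and 1 adjusted over the list alone). Their median was 0.61 (camera adjusted p = 8.13e-25, adjusted p = 0.0112 with an estimated correlation). The cone opsins included opn1lw2, red-sensitive (2.34 ± 0.19), opn1sw1, ultraviolet-sensitive (1.57 ± 0.14), opn1mw1, green-sensitive (1.38 ± 0.13) and opn1sw2, blue-sensitive (1.06 ± 0.11), with edgeR adjusted p = 7.94e-09 to 3.91e-07. 22 of 42 fatty acid oxidation and ketogenesis genes rose, 4 fell and 16 did not pass (25 and 5 adjusted over the list alone). The median was 0.62 (camera adjusted p = 3.93e-15, adjusted p = 0.0161 with an estimated correlation). Among them were angptl4, an inhibitor of lipoprotein lipase (2.5 ± 0.18), cpt1b, a carnitine palmitoyltransferase (2.71 ± 0.23) and cpt1ab, another (1.91 ± 0.15), with edgeR adjusted p = 1.53e-09 to 1.34e-08. Of 34 cholesterol synthesis and uptake genes, 18 rose, 2 fell and 14 did not pass (18 and 4 adjusted over the list alone). Their median was 0.81 (camera adjusted p = 0.000869, adjusted p = 0.366 with an estimated correlation). sqlea, squalene epoxidase, rose by 2.54 (SE 0.52, edgeR adjusted p = 0.00133), and abca1a, a cholesterol exporter, fell by 0.66 (SE 0.11, edgeR adjusted p = 0.000115). fads2, a fatty acid desaturase, rose by 2.59 (SE 0.41, edgeR adjusted p = 7.99e-05). With limma voom, sqlea did not pass (adjusted p = 0.0794).

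Acute inflammation genes fell in 18 of 29 cases and rose in 1, and 10 did not pass (20 and 1 adjusted over the list alone). The median was -0.78 (camera adjusted p = 1.79e-13, adjusted p = 0.0112 with an estimated correlation). mmp9, a matrix protease of neutrophils and inflamed tissue, and mpx, the neutrophil myeloperoxidase, were at -1.56 ± 0.22 and -1.94 ± 0.21 (edgeR adjusted p = 1.92e-05 and 4.99e-07). 15 of 27 macrophage and microglia marker genes fell, 1 rose and 11 did not pass (15 and 1 adjusted over the list alone). Their median was -0.69 (camera adjusted p = 6.53e-10, adjusted p = 0.0202 with an estimated correlation). Lower macrophage genes included grn2, a granulin (-1.74 ± 0.23), mpeg1.2, a perforin of macrophages (-1.7 ± 0.27) and marco, a scavenger receptor (-1.02 ± 0.18), with edgeR adjusted p = 8.14e-06 to 0.000354, and grna, another granulin gene outside the list, fell by 1.73 (SE 0.23, edgeR adjusted p = 1.05e-05). Of 10 antigen presentation genes, 6 fell, 0 rose and 4 did not pass (8 and 0 adjusted over the list alone). The median was -0.72 (camera adjusted p = 2.76e-06, adjusted p = 0.0297 with an estimated correlation). b2m, the shared subunit of class I molecules, fell by 1.2 (SE 0.25, edgeR adjusted p = 0.00143). Immediate early genes fell in 23 of 38 cases and rose in 0, and 15 did not pass (28 and 1 adjusted over the list alone). Their median was -0.54 (camera adjusted p = 3.93e-15, adjusted p = 0.0297 with an estimated correlation). junbb, an AP-1 subunit, fell by 0.79 (SE 0.13, edgeR adjusted p = 9.79e-05). 10 of 27 glucocorticoid and stress axis genes fell, 0 rose and 17 did not pass (11 and 0 adjusted over the list alone). The median was -0.26 (camera adjusted p = 5.51e-06, adjusted p = 0.0817 with an estimated correlation). ddit4, an inhibitor of mTOR signalling, fell by 1.08 (SE 0.15, edgeR adjusted p = 1.84e-05).

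Of the lists of nerve cell function, none of 6 passed camera, among them glutamate signalling (2 up and 0 down of 56, 1 and 0 adjusted over the list alone, median -0.034, camera adjusted p = 0.401), GABA and glycine signalling (4 up and 2 down of 46, 4 and 2 adjusted over the list alone, median 0.049, camera adjusted p = 0.45), monoamine signalling (3 up and 0 down of 55, 3 and 0 adjusted over the list alone, median -0.012, camera adjusted p = 0.992) and the presynapse (3 up and 1 down of 47, 3 and 1 adjusted over the list alone, median 0.046, camera adjusted p = 0.218). Of 33 astrocyte and radial glia genes, 13 rose, 0 fell and 20 did not pass (14 and 1 adjusted over the list alone). Their median was 0.15 (camera adjusted p = 2.5e-05, adjusted p = 0.0448 with an estimated correlation). fabp7a, a fatty acid-binding protein of radial glia, rose by 1.06 (SE 0.14, edgeR adjusted p = 7.54e-06). gc, the vitamin D-binding protein of liver, rose by 1.3 (SE 0.14, edgeR adjusted p = 4.99e-07).

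Comparing axenic with re-colonized heads asks what differs when both went through the same derivation. In experiment 1, axenic heads held more transcript of skeletal and photoreceptor genes than re-colonized heads, and less of leukocyte and antigen presentation genes. enam rose by 2.69 (SE 0.31, edgeR adjusted p = 1.39e-06), from 1.77 ± 0.402 CPM in re-colonized heads to 11.5 ± 6.74 CPM in axenic heads (SD, n = 6 each). Its value was higher in 6 of 6 axenic libraries than the re-colonized mean. angptl4 rose by 2.19 (SE 0.18, edgeR adjusted p = 7.79e-09), from 8.91 ± 3.2 CPM in re-colonized heads to 40.8 ± 9.01 CPM in axenic heads (SD, n = 6 each). It was higher in 6 of 6 axenic libraries than the re-colonized mean. nos2a fell by 6.85 (SE 0.93, edgeR adjusted p = 1.32e-05), from 18.8 ± 17.1 CPM in re-colonized heads to 0.157 ± 0.114 CPM in axenic heads (SD, n = 6 each). It was lower in 6 of 6 axenic libraries than the re-colonized mean. acod1 gave 3 counts in axenic libraries against 116 in the 6 re-colonized ones, 43.6-fold lower (95% exact interval 14.6 to 215, edgeR adjusted p = 1.12e-05). Further rises included apobb.2 (4.0 ± 0.60), cthrc1b, a collagen triple helix repeat protein (2.7 ± 0.39), ACTC1 (2.55 ± 0.38), cyp51 (2.52 ± 0.40), krtt1c19e (2.46 ± 0.24), klf11b (2.45 ± 0.21) and cpt1b (2.41 ± 0.22), with edgeR adjusted p = 1.46e-08 to 7.71e-05. Further falls included irg1l (-4.44 ± 0.58), mxf (-4.11 ± 0.68), slc2a6 (-3.03 ± 0.42), arf4b (-2.69 ± 0.44), zc3h12a (-2.6 ± 0.30) and nox1 (-2.25 ± 0.24), with edgeR adjusted p = 4.33e-07 to 0.000124. By edgeR, 3342 of 19727 genes passed, 1710 higher and 1632 lower in axenic heads, 407 and 424 of them by more than 2-fold, and 36 of 48 lists passed camera (26 upward, 10 downward), 15 with an estimated correlation and 35 by fry.

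Cartilage and bone genes rose in 35 of 56 cases and fell in 3, and 18 did not pass (35 and 3 adjusted over the list alone). The median was 0.75 (camera adjusted p = 2.44e-33, adjusted p = 0.00326 with an estimated correlation). 33 of 47 phototransduction genes rose, 0 fell and 14 did not pass (38 and 0 adjusted over the list alone). Their median was 0.63 (camera adjusted p = 3.11e-26, adjusted p = 0.00655 with an estimated correlation). Of 34 cholesterol synthesis and uptake genes, 18 rose, 3 fell and 13 did not pass (20 and 3 adjusted over the list alone). The median was 0.78 (camera adjusted p = 0.00583, adjusted p = 0.44 with an estimated correlation). Rises there included sqlea (2.24 ± 0.51) and hmgcra, the rate-limiting reductase of sterol synthesis (1.8 ± 0.33), with edgeR adjusted p = 0.00045 to 0.00307, and fads2 of fatty acid synthesis rose by 2.39 (SE 0.40, edgeR adjusted p = 0.00015). With limma voom, sqlea did not pass (adjusted p = 0.151).

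Macrophage and microglia marker genes fell in 16 of 27 cases and rose in 1, and 10 did not pass (19 and 1 adjusted over the list alone). Their median was -1.07 (camera adjusted p = 2e-17, adjusted p = 0.0038 with an estimated correlation). Values were grn2 (-2.18 ± 0.22), mpeg1.2 (-2.28 ± 0.27) and ctss2.2, a cathepsin S of the antigen presentation list too (-1.42 ± 0.18), with edgeR adjusted p = 2.66e-07 to 3.71e-06, and outside the list ctsl.1, a cathepsin L (-1.96 ± 0.17) and grna (-2.02 ± 0.23), with edgeR adjusted p = 1.56e-08 to 1.14e-06. 8 of 10 antigen presentation genes fell, 0 rose and 2 did not pass (8 and 0 adjusted over the list alone). The median was -1.22 (camera adjusted p = 1.65e-13, adjusted p = 0.00326 with an estimated correlation). mhc1zba, a class I heavy chain, and b2m were at -1.05 ± 0.11 and -2.1 ± 0.24 (edgeR adjusted p = 6.49e-07 and 1.45e-06). Of 51 fasting and amino acid stress genes, 21 fell, 3 rose and 27 did not pass (26 and 6 adjusted over the list alone). Their median was -0.26 (camera adjusted p = 4.24e-06, adjusted p = 0.0806 with an estimated correlation). trib3 and ddit3, stress genes downstream of ATF4, were at -0.84 ± 0.10 and -0.98 ± 0.12 (edgeR adjusted p = 1.5e-06 and 5.21e-06), and ddit4 at -1.08 ± 0.15 (edgeR adjusted p = 1.69e-05).

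GABA and glycine signalling genes rose in 9 of 46 cases and fell in 0, and 37 did not pass (9 and 0 adjusted over the list alone). The median was 0.11 (camera adjusted p = 0.0281, adjusted p = 0.295 with an estimated correlation). Its members slc6a9, a glycine transporter, and slc6a11b, a GABA transporter, were at 0.30 ± 0.072 and 0.39 ± 0.10 (edgeR adjusted p = 0.0053 and 0.00597). 9 of 47 presynaptic genes rose, 1 fell and 37 did not pass (10 and 1 adjusted over the list alone). Their median was 0.10 (camera adjusted p = 0.00696, adjusted p = 0.4 with an estimated correlation). snap25b, a vesicle fusion protein, rose by 0.51 (SE 0.091, edgeR adjusted p = 0.000309). Lists that did not pass included glutamate signalling (3 up and 0 down of 56, 3 and 0 adjusted over the list alone, median 0.00070, camera adjusted p = 0.816).

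Against both colonized groups, 2268 genes of experiment 1 were called in the same direction, 1294 higher and 974 lower in axenic heads, and 0 in opposite directions. These include apobb.2, enam, cyp51, cpt1b and col11a2 among the higher genes and acod1, nos2a, irg1l, mxf and nox1 among the lower. Independent calls would share 152 higher and 110 lower genes. The 10 simulations had no changed gene, so their 0 shared calls test little. Fold changes of both comparisons correlated across genes at r = 0.891 with covariance 0.213, against 0.491 and 0.0219 in the simulations. With axenic A, D and G set against conventional and axenic C, F and H against re-colonized heads, 664 higher and 350 lower genes were shared and 0 were opposite (expected 53.8 and 25.6, r = 0.745).

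**Figure D2:**
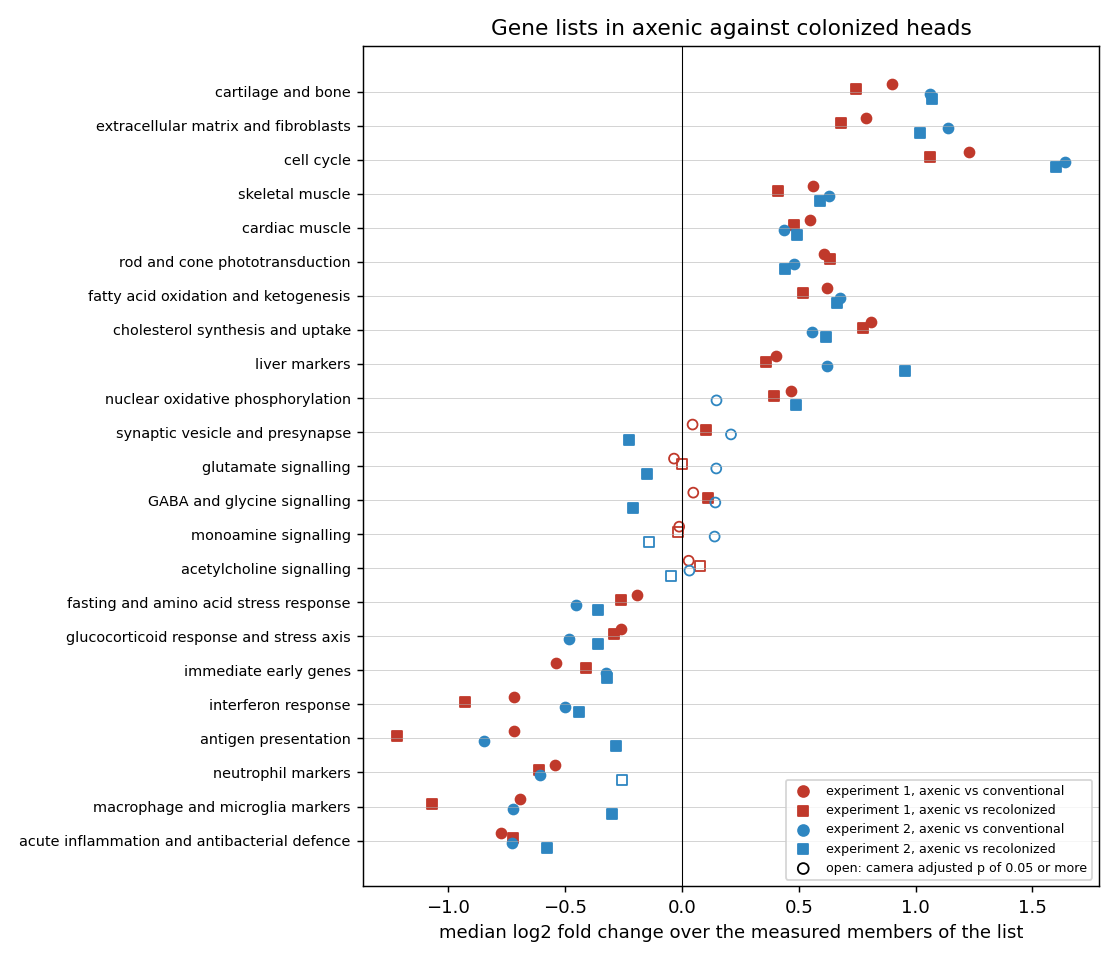
Median log2 fold change over the measured members of a selection of the 48 gene lists, for axenic against conventional heads (circles) and against re-colonized heads (squares) in experiment 1 (red) and experiment 2 (blue), with open symbols where camera did not pass. The cartilage and bone list stands at 0.90, 0.75, 1.06 and 1.07 and the macrophage and microglia list at -0.69, -1.07, -0.72 and -0.30.

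Comparing re-colonized with conventional heads asks what the derivation leaves behind once microbes are back. In experiment 1, 3 genes differed. clca1 fell by 1.86 (SE 0.28, edgeR adjusted p = 0.0128), at 1.51 ± 0.557 CPM in re-colonized heads (SD, n = 6) and 5.52 ± 1.53 CPM in conventional heads (SD, n = 6). si:ch211-69b7.6 (chromosome 11, 11891580 to 11910226) and si:dkey-7c18.24 (chromosome 20, 46039591 to 46043406), clone-named genes without a described function and named after their values were seen, rose by 0.84 (SE 0.13) and 1.06 (SE 0.17), both with edgeR adjusted p = 0.0134. In axenic heads they were at 0.065 ± 0.14 and -0.33 ± 0.17 against conventional heads (edgeR adjusted p = 0.8 and 0.206). At an unadjusted p below 0.05, 945 of 19727 genes differed, DESeq2 called 5, and edgeR called 0 without re-colonized F, 1 without conventional F and 8 without conventional B. Without re-colonized F, clca1 and si:ch211-69b7.6 did not pass (adjusted p = 0.0538 and 0.0602). Without conventional F, si:ch211-69b7.6 did not pass (adjusted p = 0.0554). si:dkey-7c18.24 did not pass without any 1 of conventional F and re-colonized D, F and G (adjusted p = 0.051 to 0.0602).

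Camera passed 15 of 48 lists, 10 higher and 5 lower in re-colonized heads, but 1 with an estimated correlation and 1 by fry. No antigen presentation gene of 10 passed (3 up and 0 down adjusted over the list alone). The median was 0.47 (camera adjusted p = 3.64e-09, adjusted p = 0.0274 with an estimated correlation). nos2a, irg1l and apobb.2, far from axenic levels in both colonized groups, were at 2.17 (SE 0.59, edgeR adjusted p = 0.643), 0.45 (SE 0.45, edgeR adjusted p = 0.999) and 0.76 (SE 0.90, edgeR adjusted p = 0.999) between them.

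In experiment 2, axenic heads again held more transcript of matrix, cartilage, cell cycle and sterol genes than conventional heads by camera, and less of macrophage, fasting and glucocorticoid response genes, but with an estimated correlation the glucocorticoid list alone of these passed (adjusted p = 0.0391, others 0.0575 to 0.368). apobb.2 rose by 5.78 (SE 0.89, edgeR adjusted p = 0.000366), from 0.645 ± 0.558 CPM in conventional heads (SD, n = 7) to 33.6 ± 36 CPM in axenic heads (SD, n = 4). It was higher in 4 of 4 axenic libraries than the conventional mean. cyp51 rose by 2.93 (SE 0.37, edgeR adjusted p = 7.39e-05), from 3.76 ± 1.3 CPM in conventional heads (SD, n = 7) to 28.6 ± 18.6 CPM in axenic heads (SD, n = 4). Its value was higher in 4 of 4 axenic libraries than the conventional mean. irg1l fell by 4.73 (SE 0.78, edgeR adjusted p = 0.000729), from 103 ± 100.1 CPM in conventional heads (SD, n = 7) to 3.89 ± 2.32 CPM in axenic heads (SD, n = 4). It was lower in 4 of 4 axenic libraries than the conventional mean. oxgr1a.1, a receptor for oxoglutarate, gave 0 counts in the 4 axenic libraries against 214 in the 7 conventional ones, at least 48.7-fold lower with 3 counts over the group as the floor (edgeR adjusted p = 0.00157).

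Rises against both colonized groups also included hpx, the heme carrier hemopexin (4.24 ± 0.84), cthrc1b (3.75 ± 0.74), gck, glucokinase (3.11 ± 0.61), col7a1, the collagen of anchoring fibrils (3.03 ± 0.58), enam (2.86 ± 0.48), col10a1b, a collagen X gene (2.8 ± 0.63) and tk1, thymidine kinase (2.75 ± 0.64), with edgeR adjusted p = 0.000843 to 0.0111. Falls included urgcp (-3.49 ± 0.40), plekhs1 (-3.08 ± 0.64), nupr1b, a stress-induced nuclear protein (-3.06 ± 0.52), nfkbiz, an inducible IκB family regulator (-2.79 ± 0.45), pmaip1, a pro-apoptotic BH3 protein (-2.37 ± 0.40) and trim63a, a ubiquitin ligase of wasting muscle (-2.55 ± 0.31), with edgeR adjusted p = 2.25e-05 to 0.00461. Other large differences were those of nos2a (-5.87 ± 1.18), postnb, a periostin (3.23 ± 0.43), sc5d, a late enzyme of sterol synthesis (3.27 ± 0.76) and isg15, an interferon-induced ubiquitin-like protein (-3.77 ± 1.05), with edgeR adjusted p = 8.9e-05 to 0.0329. Without axenic 7, hpx, cthrc1b, tk1 and sc5d did not pass (adjusted p = 0.132, 0.0519, 0.14 and 0.23). isg15 did not pass without any 1 of axenic 3, 4 and 7 and conventional 2 and 3 (adjusted p = 0.0503 to 0.137). With limma voom, nos2a and sc5d did not pass (adjusted p = 0.0921 and 0.094).

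By edgeR's quasi-likelihood test, 1237 of 20169 genes passed, 804 higher and 433 lower in axenic heads (592 and 280 by more than 2-fold), while DESeq2 called 1903 (973 and 930) and limma voom 2068 (1191 and 877). Without axenic 7 edgeR called 391 (223 and 168), 382 of them among the 1237, and without conventional 3 it called 821. Camera passed 27 of 48 lists, 16 upward and 11 downward, with 1 left with an estimated correlation and 16 by fry. Glucocorticoid and stress axis genes fell in 6 of 27 cases and rose in 0, and 21 did not pass (8 and 0 adjusted over the list alone). Their median was -0.48 (camera adjusted p = 7.82e-06, adjusted p = 0.0391 with an estimated correlation). Values were tsc22d3, the glucocorticoid-induced leucine zipper (-1.34 ± 0.20), ddit4 (-1.98 ± 0.34) and klf9, a glucocorticoid-induced factor (-1.35 ± 0.34), with edgeR adjusted p = 0.00033 to 0.0176. Without axenic 1, klf9 did not pass (adjusted p = 0.0551). Without axenic 7, klf9 did not pass (adjusted p = 0.0988).

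37 of 64 matrix and fibroblast genes rose, 0 fell and 27 did not pass (47 and 0 adjusted over the list alone). The median was 1.14 (camera adjusted p = 4.65e-37, adjusted p = 0.0575 with an estimated correlation). Values were col6a3, a microfibrillar collagen (3.11 ± 0.34), lum, lumican (2.52 ± 0.29) and col5a1 (2.0 ± 0.26), with edgeR adjusted p = 2.25e-05 to 7.93e-05. Of 58 cartilage and bone genes, 27 rose, 1 fell and 30 did not pass (34 and 5 adjusted over the list alone). Their median was 1.06 (camera adjusted p = 6.09e-17, adjusted p = 0.122 with an estimated correlation). Values were hapln1a, a cartilage link protein (2.73 ± 0.31) and ifitm5 (3.06 ± 0.41), with edgeR adjusted p = 2.25e-05 to 9.59e-05. Cell cycle genes rose in 30 of 53 cases and fell in 0, and 23 did not pass (46 and 1 adjusted over the list alone). The median was 1.64 (camera adjusted p = 1.51e-33, adjusted p = 0.0575 with an estimated correlation). Values were mki67, the proliferation marker Ki-67 (2.66 ± 0.34), mcm3 (2.11 ± 0.29), mcm5 (2.13 ± 0.39) and uhrf1 (2.12 ± 0.33), with edgeR adjusted p = 7.63e-05 to 0.00172. 9 of 35 cholesterol synthesis and uptake genes rose, 3 fell and 23 did not pass (16 and 3 adjusted over the list alone). Their median was 0.56 (camera adjusted p = 0.000806, adjusted p = 0.368 with an estimated correlation). Values were hmgcra (2.82 ± 0.35), sqlea (2.54 ± 0.47) and srebf1, a sterol and fatty acid regulator (-1.25 ± 0.18), with edgeR adjusted p = 4.71e-05 to 0.00181. Of 43 fatty acid oxidation and ketogenesis genes, 12 rose, 1 fell and 30 did not pass (20 and 6 adjusted over the list alone). The median was 0.68 (camera adjusted p = 2.58e-06, adjusted p = 0.122 with an estimated correlation). Values were hadhab, a trifunctional protein subunit (1.58 ± 0.19), cpt1ab (2.09 ± 0.27), angptl4 (2.49 ± 0.36) and cpt1b (1.86 ± 0.32), with edgeR adjusted p = 3.53e-05 to 0.000843.

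Phototransduction genes rose in 10 of 48 cases and fell in 0, and 38 did not pass (14 and 0 adjusted over the list alone). Their median was 0.48 (camera adjusted p = 5.39e-06, adjusted p = 0.167 with an estimated correlation). Values were opn1mw1 (2.42 ± 0.31) and opn1lw2 (2.18 ± 0.38), with edgeR adjusted p = 7.63e-05 to 0.00108. 5 of 28 macrophage and microglia marker genes fell, 0 rose and 23 did not pass (6 and 1 adjusted over the list alone). The median was -0.72 (camera adjusted p = 4.44e-06, adjusted p = 0.219 with an estimated correlation). Values were mpeg1.2 (-2.94 ± 0.53) and marco (-2.39 ± 0.40), with edgeR adjusted p = 0.000843 to 0.00155. Of 51 fasting and amino acid stress genes, 17 fell, 0 rose and 34 did not pass (20 and 2 adjusted over the list alone). Their median was -0.45 (camera adjusted p = 2.78e-10, adjusted p = 0.0575 with an estimated correlation). Values were sesn1, a sestrin that holds back mTOR (-1.46 ± 0.19) and trib3 (-1.31 ± 0.20), with edgeR adjusted p = 7.49e-05 to 0.000396. Lists of nerve cell function that did not pass included glutamate signalling (2 up and 0 down of 56, 1 and 0 adjusted over the list alone, median 0.15, camera adjusted p = 0.178) and GABA and glycine signalling (1 up and 0 down of 47, 1 and 0 adjusted over the list alone, median 0.14, camera adjusted p = 0.746).

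**Figure D3:**
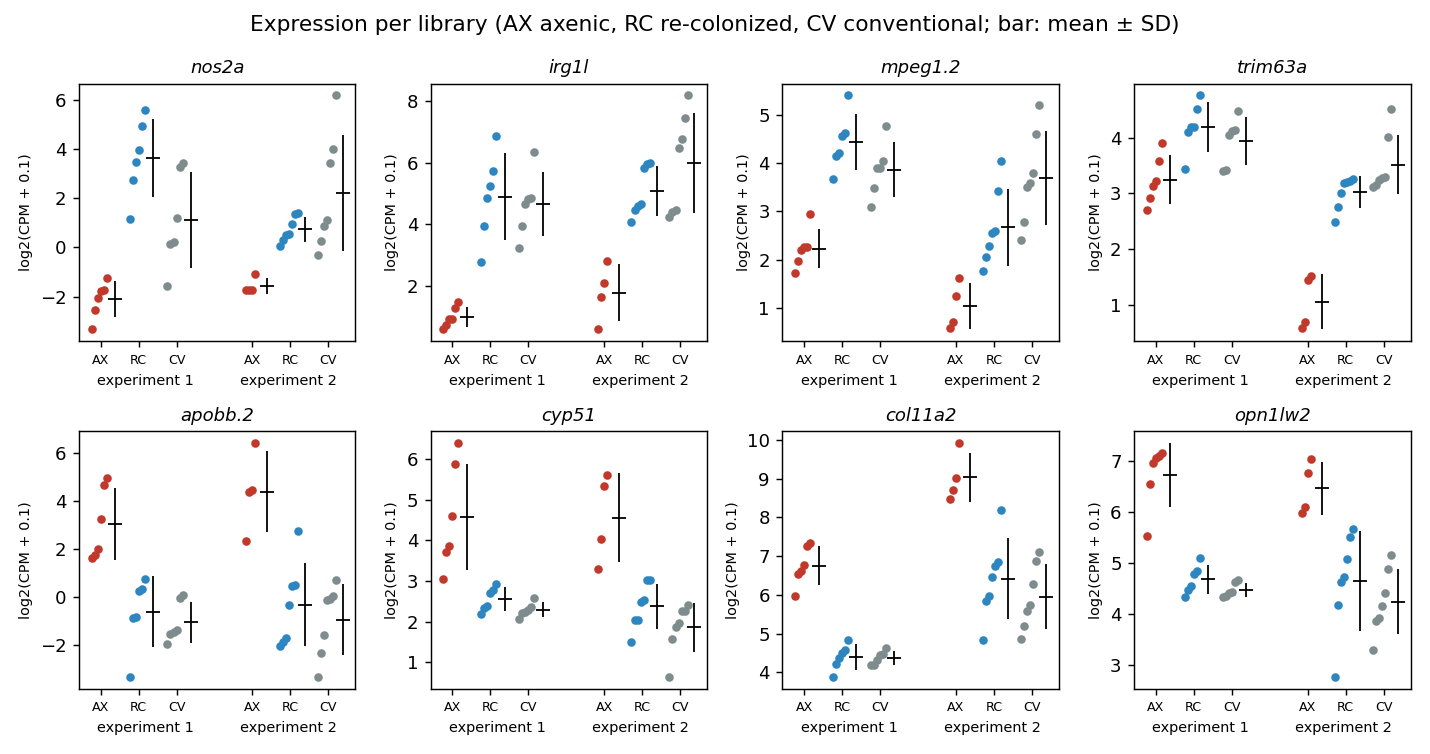
Expression of 8 genes as log2(CPM + 0.1) in each library of both experiments, with points for libraries and bars for mean ± SD of axenic (AX), re-colonized (RC) and conventional (CV) heads. Mean irg1l CPM was 1.95 in axenic against 42.8 and 31.3 in re-colonized and conventional heads of experiment 1, and 3.89 against 38.7 and 103 in experiment 2.

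Against re-colonized heads of experiment 2, axenic heads held more transcript of cell cycle, skeletal and liver genes by camera, but with an estimated correlation the cell cycle list alone of these passed (adjusted p = 0.047, others 0.0507 each). cyp51 rose by 2.4 (SE 0.37, edgeR adjusted p = 0.000516), from 5.42 ± 2.04 CPM in re-colonized heads (SD, n = 7) to 28.6 ± 18.6 CPM in axenic heads (SD, n = 4). Its value was higher in 4 of 4 axenic libraries than the re-colonized mean. urgcp fell by 2.81 (SE 0.38, edgeR adjusted p = 0.000279), from 12.2 ± 3.66 CPM in re-colonized heads (SD, n = 7) to 1.74 ± 0.600 CPM in axenic heads (SD, n = 4). It was lower in 4 of 4 axenic libraries than the re-colonized mean. oxgr1a.1 gave 0 counts in axenic libraries against 134 in the 7 re-colonized ones, at least 22.1-fold lower with the same floor (edgeR adjusted p = 0.0105). Further rises included apobb.2 (4.49 ± 0.81), enam (2.74 ± 0.48), hpx (4.04 ± 0.81), gck (3.27 ± 0.60), cthrc1b (3.01 ± 0.70), col7a1 (2.89 ± 0.57), col10a1b (2.88 ± 0.62) and tk1 (2.8 ± 0.63), with edgeR adjusted p = 0.00178 to 0.0154. Further falls included irg1l (-3.31 ± 0.73), nfkbiz (-2.25 ± 0.44), plekhs1 (-2.48 ± 0.63), nupr1b (-2.45 ± 0.51), pmaip1 (-2.28 ± 0.40) and trim63a (-1.98 ± 0.31), with edgeR adjusted p = 0.000652 to 0.0258. Without axenic 7, apobb.2, hpx, cthrc1b, col7a1, tk1, oxgr1a.1, irg1l and nupr1b did not pass (adjusted p = 0.0501, 0.215, 0.184, 0.0662, 0.161, 0.0662, 0.0775 and 0.0538). Without axenic 4, gck did not pass (adjusted p = 0.05). plekhs1 did not pass without any 1 of axenic 1, 4 and 7 and re-colonized 3 (adjusted p = 0.0545 to 0.15). Without re-colonized 1 and 7, cthrc1b and plekhs1 did not pass (adjusted p = 0.0757 and 0.0693). With limma voom, plekhs1 did not pass (adjusted p = 0.0768).

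By edgeR, 785 of 20169 genes passed, 656 higher and 129 lower in axenic heads (511 and 71 by more than 2-fold). The count was 165 (139 and 26) without axenic 7, 164 of them among the 785, and 418 without axenic 4, 473 without re-colonized 3, 451 without re-colonized 7 and 368 without re-colonized 1 and 7. Camera passed 33 of 48 lists (22 upward, 11 downward), 1 with an estimated correlation and 23 by fry. Cell cycle genes rose in 31 of 53 cases and fell in 0, and 22 did not pass (45 and 0 adjusted over the list alone). The median was 1.6 (camera adjusted p = 1.3e-46, adjusted p = 0.047 with an estimated correlation). Values were mki67 (2.25 ± 0.34), mcm5 (2.21 ± 0.39), mcm3 (2.11 ± 0.29) and uhrf1 (1.91 ± 0.32), with edgeR adjusted p = 0.000312 to 0.00194. 27 of 58 cartilage and bone genes rose, 0 fell and 31 did not pass (31 and 0 adjusted over the list alone). Their median was 1.07 (camera adjusted p = 4.04e-23, adjusted p = 0.0507 with an estimated correlation). Of 60 liver marker genes, 24 rose, 0 fell and 36 did not pass (36 and 0 adjusted over the list alone). The median was 0.95 (camera adjusted p = 4.04e-23, adjusted p = 0.0507 with an estimated correlation). Values were a2ml, an alpha-2-macroglobulin-like protein (2.88 ± 0.37), tfa, transferrin (2.58 ± 0.33) and c9, a terminal complement protein (1.84 ± 0.29), with edgeR adjusted p = 0.000174 to 0.000736.

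Fasting and amino acid stress genes fell in 11 of 51 cases and rose in 2, and 38 did not pass (19 and 5 adjusted over the list alone). Their median was -0.36 (camera adjusted p = 6.2e-07, adjusted p = 0.0543 with an estimated correlation). Values were sesn1 (-1.33 ± 0.19) and trib3 (-1.14 ± 0.20), with edgeR adjusted p = 0.000319 to 0.00206. 4 of 28 macrophage and microglia marker genes fell, 0 rose and 24 did not pass (4 and 1 adjusted over the list alone). The median was -0.30 (camera adjusted p = 0.00465, adjusted p = 0.338 with an estimated correlation). No presynaptic gene of 49 passed (0 up and 0 down adjusted over the list alone). Their median was -0.23 (camera adjusted p = 0.00801, adjusted p = 0.544 with an estimated correlation). No glutamate signalling gene of 56 passed (0 up and 0 down adjusted over the list alone). The median was -0.15 (camera adjusted p = 0.00285, adjusted p = 0.523 with an estimated correlation). 1 of 47 GABA and glycine signalling genes rose, 0 fell and 46 did not pass (0 and 0 adjusted over the list alone). Their median was -0.21 (camera adjusted p = 0.0176, adjusted p = 0.56 with an estimated correlation).

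In experiment 2, 570 genes were called in the same direction against both colonized groups, 467 higher (expected 26.2 for independent calls) and 103 lower (expected 2.77), and 0 in opposite directions. The 10 simulations without changed genes again gave at most 0. Fold changes correlated across genes at r = 0.763 with covariance 0.284, against 0.644 and 0.105 in the simulations. These leave out any deviation shared by real axenic libraries. With axenic 1 and 4 against conventional and axenic 3 and 7 against re-colonized heads, 101 higher and 19 lower genes were shared and 0 were opposite (expected 2.48 and 0.0821, r = 0.529). The count was 126 without axenic 7, 323 without axenic 4, 357 without re-colonized 3, 364 without re-colonized 7 and 325 without re-colonized 1 and 7.

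Between re-colonized and conventional heads of experiment 2, no gene passed, and the glutamate signalling list stood higher and the ribosomal and liver lists lower in re-colonized heads by camera, but not with an estimated correlation (adjusted p = 0.602 each). edgeR called 0 of 20169 genes, with 2751 at an unadjusted p below 0.05, while DESeq2 called 119 (23 higher, 96 lower) and limma voom 118 (21 and 97). clca1 was at -2.74 (SE 0.84, edgeR adjusted p = 0.259), nos2a at -3.15 (SE 0.76, edgeR adjusted p = 0.239) and apobb.2 at 1.29 (SE 0.82, edgeR adjusted p = 0.473). Camera passed 19 of 48 lists, 5 higher and 14 lower, but 0 with an estimated correlation and 0 by fry. No glutamate signalling gene of 56 passed (2 up and 0 down adjusted over the list alone). The median was 0.36 (camera adjusted p = 4.29e-09, adjusted p = 0.602 with an estimated correlation). No ribosomal protein gene of 79 passed (0 up and 0 down adjusted over the list alone). Their median was -0.45 (camera adjusted p = 8.37e-10, adjusted p = 0.602 with an estimated correlation). No liver marker gene of 60 passed (0 up and 4 down adjusted over the list alone). The median was -0.39 (camera adjusted p = 4.19e-09, adjusted p = 0.602 with an estimated correlation).

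The 2 experiments used different RNA chemistry and extraction, which asks which differences appear in both. Higher genes, with values for experiments 1 and 2, included apobb.2 (4.76 ± 0.65 and 5.78 ± 0.89), enam (3.04 ± 0.32 and 2.86 ± 0.48), cyp51 (2.8 ± 0.41 and 2.93 ± 0.37), krtt1c19e (2.86 ± 0.24 and 2.58 ± 0.47), col11a2 (2.45 ± 0.18 and 2.99 ± 0.48), sqlea (2.54 ± 0.52 and 2.54 ± 0.47), angptl4 (2.5 ± 0.18 and 2.49 ± 0.36) and col10a1a (2.43 ± 0.21 and 3.17 ± 0.49), with edgeR adjusted p = 1.53e-09 to 0.00181. Lower genes included nos2a (-4.68 ± 1.07 and -5.87 ± 1.18), irg1l (-4.0 ± 0.58 and -4.73 ± 0.78), slc2a6 (-2.87 ± 0.43 and -2.42 ± 0.51), nox1 (-2.21 ± 0.24 and -2.41 ± 0.41), urgcp (-2.2 ± 0.34 and -3.49 ± 0.40), acp5a (-1.77 ± 0.27 and -1.79 ± 0.51), nr0b2a (-2.0 ± 0.23 and -1.76 ± 0.43) and grna (-1.73 ± 0.23 and -1.73 ± 0.38), with edgeR adjusted p = 5.3e-07 to 0.0374. nr0b2a encodes the small heterodimer partner, a nuclear receptor that represses bile acid synthesis. Of 18768 genes tested in both, 482 were higher in both (expected 67.1 for independent lists, Fisher's exact p below 1e-300) and 220 lower in both (expected 28.3, Fisher's exact p = 5.66e-147), with 0 opposite. Without axenic 7 of experiment 2, the count was 284. Fold changes correlated across genes at r = 0.613, and genes are not independent replicates. Without axenic 1, nr0b2a did not pass (adjusted p = 0.0537). Without axenic 7, grna did not pass (adjusted p = 0.053). acp5a did not pass without any 1 of axenic 1, 4 and 7 and conventional 2, 6 and 7 (adjusted p = 0.0604 to 0.126). With limma voom, sqlea and nos2a of either experiment did not pass (adjusted p = 0.0794, 0.212 and 0.0921). With the 2 groups alone, acp5a did not pass (adjusted p = 0.0644).

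Against re-colonized heads, genes higher in axenic heads of both experiments included apobb.2 (4.0 ± 0.60 and 4.49 ± 0.81), enam (2.69 ± 0.31 and 2.74 ± 0.48), cyp51 (2.52 ± 0.40 and 2.4 ± 0.37), col11a2 (2.4 ± 0.18 and 2.39 ± 0.47), cthrc1b (2.7 ± 0.39 and 3.01 ± 0.70), sqlea (2.24 ± 0.51 and 2.88 ± 0.47), col10a1a (2.23 ± 0.20 and 2.57 ± 0.49) and fads2 (2.39 ± 0.40 and 2.37 ± 0.46), with edgeR adjusted p = 5.19e-09 to 0.0154. Lower genes included irg1l (-4.44 ± 0.58 and -3.31 ± 0.73), urgcp (-2.56 ± 0.34 and -2.81 ± 0.38), plekhs1 (-1.9 ± 0.38 and -2.48 ± 0.63), nfkbiz (-1.22 ± 0.13 and -2.25 ± 0.44), nox1 (-2.25 ± 0.24 and -1.69 ± 0.39), mpeg1.2 (-2.28 ± 0.27 and -1.83 ± 0.51), stat4 (-2.06 ± 0.25 and -1.45 ± 0.35) and ctsl.1 (-1.96 ± 0.17 and -1.34 ± 0.35), with edgeR adjusted p = 1.56e-08 to 0.0428, where stat4 encodes a transcription factor of cytokine signalling. In all 514 genes were called alike, 416 higher (expected 53.9, Fisher's exact p below 1e-300) and 98 lower (expected 10.6, Fisher's exact p = 1.68e-79), with r = 0.594 across genes, 140 without axenic 7 and 279 without re-colonized 1 and 7 of experiment 2. The 1 gene called in opposite directions, named after its values were seen, was capn9, a calpain of the digestive tract, at -0.48 ± 0.15 and 1.32 ± 0.28 (edgeR adjusted p = 0.0292 and 0.00799). Without axenic 7, apobb.2, col11a2, cthrc1b, fads2, irg1l, nox1 and capn9 did not pass (adjusted p = 0.0501, 0.0598, 0.184, 0.0916, 0.0775, 0.111 and 0.0786). Without axenic 3, nox1 did not pass (adjusted p = 0.0548). plekhs1 did not pass without any 1 of axenic 1, 4 and 7 and re-colonized 3 (adjusted p = 0.0545 to 0.15). mpeg1.2 did not pass without any 1 of axenic 1, 3, 4 and 7 and re-colonized 1, 3, 4 and 7 (adjusted p = 0.0563 to 0.222). stat4 did not pass without any 1 of axenic 3, 4 and 7 (adjusted p = 0.0509 to 0.101). ctsl.1 did not pass without any 1 of axenic 1, 3, 4 and 7 and re-colonized 1, 2, 4, 5 and 7 (adjusted p = 0.0514 to 0.105). capn9 did not pass without any 1 of axenic C, D and H and re-colonized D and G (adjusted p = 0.0509 to 0.087). Without re-colonized 1 and 7, cthrc1b, plekhs1, mpeg1.2, ctsl.1 and capn9 did not pass (adjusted p = 0.0757, 0.0693, 0.0968, 0.089 and 0.0548). With limma voom, sqlea, plekhs1 and mpeg1.2 did not pass (adjusted p = 0.151, 0.0768 and 0.108).

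Over all 4 comparisons of axenic with colonized heads, 313 genes were higher and 81 lower. Lists that passed camera in both experiments had the same direction in 24 of 26 cases against conventional heads. Against re-colonized heads 27 of 29 did, and between colonized groups 1 of 9. With an estimated correlation, 0 lists passed in both. Lens crystallins, for one, had medians of 0.18 in experiment 1 and -0.56 in experiment 2 against conventional heads, and the difference passed camera (adjusted p = 1.56e-09) but not with an estimated correlation (adjusted p = 0.911). The effect against conventional heads differed between experiments for 21 of 21208 genes by edgeR's interaction test, 14 with the value of experiment 1 above and 7 with it below, and for 125 by limma voom and 42 by edgeR without re-colonized 1 and 7. These genes include nupr1b (-0.13 and -3.06 in experiments 1 and 2, difference 3.01, edgeR adjusted p = 0.0117) and, at 0.031 each, trim63a (-0.70 and -2.55, difference 1.92), sesn1 (-0.48 and -1.46, 1.03) and tsc22d3 (-0.37 and -1.34, 1.03). anpepb, an intestinal aminopeptidase named after its values were seen, fell by 2.15 in experiment 1 and was at 1.02 in experiment 2 (edgeR adjusted p = 6.74e-07 and 0.306), a difference of -3.08 (edgeR adjusted p = 0.0356). Against re-colonized heads 0 genes differed between experiments by edgeR (1551 at an unadjusted p below 0.05, 1 by limma voom), and between colonized groups 0 did (2607 and 184, and 1 by edgeR without re-colonized 1 and 7), where 0 genes were called in both experiments and fold changes correlated across genes at r = -0.0956.

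**Figure D4:**
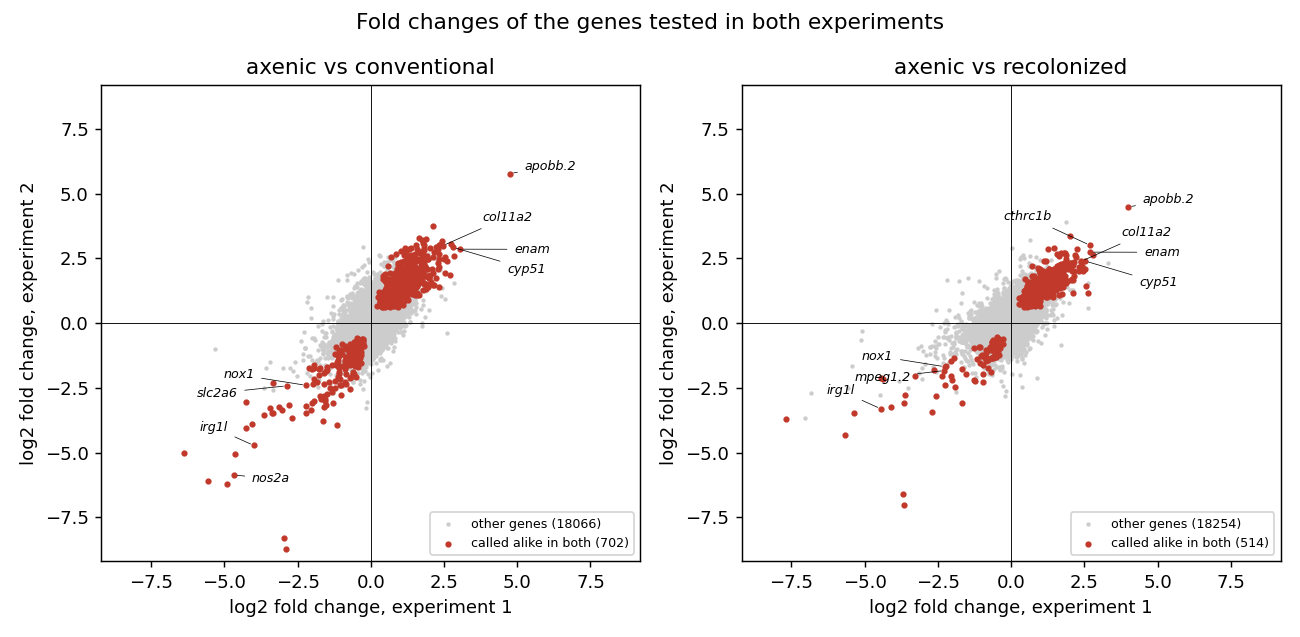
Log2 fold change in experiment 1 (horizontal axis) and experiment 2 (vertical axis) of each gene tested in both, for axenic against conventional (left) and re-colonized heads (right), with genes called in the same direction in both in red. Among the red genes of the left panel, nos2a lies at -4.68 and -5.87 and apobb.2 at 4.76 and 5.78.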

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

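The tests of the 3 patterns weighed here, the splits for genes and lists of axenic against conventional heads of experiment 1, and leaving out structural RNAs or re-colonized 1 and 7, were chosen only after the result was seen.

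By a test of the gap to the nearest library of the same group against the group's range, 74 of 849 groups of values (8.72%, where chance gives about 5%) had a library apart. List scores are mean log2 CPM of the members, and other values are CPM. In experiment 1, axenic A was highest in the skin and mucosal epithelium score (4.98 against 4.59 to 4.74), cpt1b (16.4 against 8.74 to 10.9) and ifitm5 (4.25 against 1.03 to 1.74), and lowest in the immediate early genes score (3.5 against 3.83 to 4.02). Re-colonized B was highest in ctss2.2 (15.6 against 8.05 to 10.8) and irf1b (8.13 against 2.36 to 4.39), and lowest in the astrocyte and radial glia markers score (3.76 against 3.97 to 4.08) and ptgdsb.2 (15.5 against 23.1 to 27.3). Axenic G was highest in acp5a (2.05 against 0.738 to 1.11), mpeg1.2 (7.6 against 3.2 to 4.69) and grn2 (5.47 against 2.13 to 3.2). Conventional B was highest in grna (34 against 11.1 to 18.6) and mki67 (8.95 against 3.77 to 5.33), and lowest in the GABA and glycine signalling score (3.32 against 3.44 to 3.5). Re-colonized D was highest in arf4b (50.6 against 5.05 to 18.7) and mylipa (119 against 90.9 to 99.9), and lowest in lum (1.52 against 2.17 to 2.43). Re-colonized F was highest in klf11b (3.61 against 1.68 to 2.11) and abca1a (844 against 562 to 613), and lowest in cpt1ab (4.08 against 6.29 to 7.32). Conventional A was highest in junbb (104 against 68.6 to 78.4) and ccr9a (5.21 against 2.63 to 3.24). Conventional H was highest in irg1l (80.5 against 9.39 to 29) and trib3 (56.8 against 41.7 to 46.7). Axenic C was highest in pvalb4 (109 against 63.9 to 76.1). Axenic D was highest in mxf (0.426 against 0 to 0.139). Axenic H was lowest in the neural progenitor and neurogenesis score (3.27 against 3.6 to 3.77). Conventional C was highest in hapln1a (7.53 against 4.46 to 5.45). Conventional F was lowest in the lipoproteins and lipid transport score (4.46 against 4.74 to 4.88). Conventional G was lowest in ifitm5 (0 against 0.266 to 0.405).

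In experiment 2, re-colonized 6 was highest in apobb.2 (6.64 against 0.143 to 1.32), col11a2 (294 against 28.3 to 115), cthrc1b (1.9 against 0.0885 to 0.559), col7a1 (4.9 against 0.429 to 2.03), tk1 (2.31 against 0.0358 to 0.844), uhrf1 (11.1 against 4.2 to 6.57), mki67 (23.2 against 5.61 to 11.8) and ptgdsb.2 (59.8 against 22.1 to 38.2). Conventional 1 was highest in opn1sw1 (3650 against 1110 to 1700), hmgcra (18.4 against 7.95 to 12.4), hapln1a (6.34 against 3.2 to 4.5) and a2ml (46.7 against 12.4 to 26.6), and lowest in the glucocorticoid response and stress axis score (3.71 against 4.04 to 4.24), the exocrine pancreas markers score (4.05 against 5.92 to 7.24) and the ribosomal proteins score (6.79 against 7.9 to 8.74). Conventional 7 was highest in klf11b (11.1 against 4.61 to 7.02), cpt1b (7.53 against 1.76 to 3.71), nos2a (71.9 against 0.712 to 15.9), cthrc1b (1.15 against 0 to 0.431), angptl4 (18.8 against 3.65 to 9.59), ctss2.2 (14.3 against 3.37 to 7.57) and ptgdsb.2 (45.9 against 20.9 to 30.7). Re-colonized 1 was lowest in the neutrophil markers score (1.01 against 1.9 to 2.39), the glucocorticoid response and stress axis score (3.41 against 3.87 to 4.14), the xenobiotic metabolism and aryl hydrocarbon response score (2.06 against 2.49 to 2.69), the exocrine pancreas markers score (1.63 against 4.91 to 7.1), the mitochondrially encoded genes score (7.24 against 7.97 to 8.47) and the intestine markers score (1.98 against 3.15 to 3.99). Conventional 2 was highest in krtt1c19e (320 against 76.3 to 157), hpx (0.885 against 0 to 0.353), col10a1a (133 against 26.6 to 63.7), mpx (227 against 57.4 to 117) and isg15 (8.52 against 0.332 to 1.66). Axenic 3 was highest in nos2a (0.368 against 0.199 to 0.201) and pmaip1 (0.491 against 0.199 to 0.201). Axenic 4 was highest in gck (10.7 against 1.49 to 2.9), and lowest in col10a1a (340 against 518 to 540). Axenic 7 was highest in slc2a6 (0.755 against 0.199 to 0.268) and mcm3 (100 against 52.7 to 56.2). Conventional 4 was highest in cyt1l (84.8 against 27.6 to 48.6) and cyt1 (524 against 281 to 381). Re-colonized 2 was highest in cpt1b (4.37 against 2.04 to 2.59) and isg15 (1.63 against 0.0352 to 0.447). Re-colonized 4 was highest in mmp9 (107 against 9.75 to 40.1).

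The effect of axenic against conventional heads differed between experiments for 21 genes by edgeR's interaction test, among them anpepb (experiment 1 minus experiment 2, -3.08), nupr1b (3.01), trim63a (1.92), sesn1 (1.03) and tsc22d3 (1.03). Chance stays open for this count, as 3 of 50 splits, the real grouping included, gave as many genes.

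By camera, the cartilage, matrix and cell cycle lists stood higher and the macrophage list lower in axenic heads of both experiments, though with an estimated correlation the cell cycle list did not pass in experiment 1 (adjusted p = 0.0937 and 0.124), nor any in experiment 2 (adjusted p = 0.0507 to 0.338) but cell cycle against re-colonized heads (adjusted p = 0.047). A batch marked by L6 or L7 in the library names is argued against, since axenic and re-colonized libraries share L6 and re-colonized (L6) against conventional (L7) heads gave 3 genes, as are structural RNAs, without which 3289 of 3342 genes (98.4%) remained called. A smaller share of brain would raise cells outside it, which is argued against in experiment 1 for leukocytes, as the neutrophil list was lower than in re-colonized heads (median -0.612, camera adjusted p = 0.019 with an estimated correlation). For the tissue lists it is argued against as the whole cause, since 9 fixed lists of head tissue outside the brain moved apart, from -0.254 (ionocytes and gill) to 0.808 (cartilage) in experiment 1 and 0.0516 to 1.09 in experiment 2 against re-colonized heads (SD of the shifts 0.33 and 0.347, exact permutation p = 0.00216 and 0.00303, the smallest possible, adjusted p = 0.00303 each by Benjamini-Hochberg over 4 tests), while a share in it stays open. Effects of absent microbes through stage, size or feeding stay open and untested, as does tissue from behind the head for the liver list.

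Without axenic 7, edgeR called 391 in place of 1237 genes in axenic against conventional heads of experiment 2. A smaller number of axenic libraries as the whole cause is argued against, since 893 to 1116 genes were called without axenic 1, 3 or 4, and library size is too, since its total of 20839573 counts lay within the 15148058 to 25760592 of the other libraries. Of 2915 genes called in experiment 1, axenic 7 alone had the same sign against the conventional mean in 80.6%, near axenic 1, 3 and 4 (80.8% to 85.8%) and above conventional libraries against each other (40.5% to 62.2%), so it shares the axenic difference, but this does not test a deviation added to it, which stays open. A biological difference of this pool stays open.

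In re-colonized against conventional heads of experiment 2, glutamate and presynaptic lists stood higher and ribosomal and liver lists lower by camera, but not with an estimated correlation (adjusted p = 0.602 each) or by fry. A difference held by both experiments is argued against by the correlation of fold changes across genes (r = -0.0956). An axis that also runs between libraries within groups, with 25.4% of that variance, stays open as an account. The fold change followed that axis at an absolute r of 0.488, short of the bound set for this test, so it does not decide it. A bias by gene length cannot be told apart from the axis, with a Spearman correlation with genomic span of 0.176 for the fold change and 0.172 for the axis. An effect of derivation stays open.

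Over other splits of the libraries, chance can be excluded where under 5% of splits gave a result as large. That held, with the real grouping the 1 of 100 splits as large, for genes of axenic against conventional (3077, highest other 1160) and re-colonized heads (3342, highest other 1102) and against both (2268, highest other 0) in experiment 1, the same in experiment 2 (1237, highest other 194, 785, highest other 35 and 570, highest other 0), genes called in both experiments (482 higher and 220 lower, highest other 0 and 514, highest other 0), and lists of axenic against re-colonized heads of experiment 1 (36, highest other 35). It also held for lists of axenic against conventional heads of experiment 1 (3 of 100, 35, highest other 38). Re-colonized against conventional genes of experiment 1 met it too (2 of 100, 3, highest other 13). Chance stays open there, as another split gave more and 0 passed without re-colonized F. Chance could not be excluded for lists of re-colonized against conventional heads of experiment 1 (29 of 100, 15, highest other 24). Nor could it for the lists of experiment 2 (17 of 100, 27, highest other 31, 5 of 100, 33, highest other 35, and 39 of 100, 19, highest other 34). The same holds for differences between experiments against conventional heads (3 of 50, 21, highest other 516). Splits say nothing where the real count was 0, as for re-colonized against conventional genes of experiment 2 (100 of 100, highest other 0) and of both experiments (100 of 100, highest other 0), and differences between experiments against re-colonized heads (50 of 50, highest other 559) and between colonized groups (50 of 50, highest other 1), and the splits with 516 and 559 genes point to a structure of the samples.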

How the results depend on the processing

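Leaving out structural RNAs, re-colonized 1 and 7, or axenic 7 for counts across experiments, was chosen only after the result was seen. Of 391 values of named genes, those that no longer passed numbered 0 with DESeq2, 18 with limma voom, 2 with DESeq2's size factors in edgeR, 3 without a filter, 7 with the block and 4 without structural RNAs, and of those run, 0 of 380 at a mean of 1 CPM, 7 of 384 with the 2 groups alone and 20 of 177 without re-colonized 1 and 7, and 0 turned direction. Over all fits that leave out 1 library, 4280 values kept direction and side of the threshold, 240 no longer passed and 4 newly passed. Of 165 list results, 132 no longer passed with an estimated correlation, 63 with fry, 9 at a mean of 1 CPM, 7 with the block, 1 with DESeq2's size factors and 2 without structural RNAs, and 12 of the 79 run without re-colonized 1 and 7, of which 2 turned direction.

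Counts moved by more than 1.5 times as follows, and the cause was not tested except where fewer libraries were fitted. In experiment 1, re-colonized against conventional genes numbered 5 by DESeq2 in place of 3. In experiment 2, axenic against conventional genes numbered 2068 by limma voom and 1903 by DESeq2 in place of 1237, and re-colonized against conventional genes 118 and 119 in place of 0. Without re-colonized 1 and 7, axenic against re-colonized genes numbered 368 in place of 785, genes against both colonized groups 325 in place of 570, and genes of axenic against re-colonized heads in both experiments 279 in place of 514. Differences between experiments against conventional heads numbered 125 by limma voom and 42 without re-colonized 1 and 7 in place of 21, those against re-colonized heads 1 by limma voom in place of 0, and those between colonized groups 184 by limma voom and 1 without re-colonized 1 and 7 in place of 0.

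With an estimated correlation, lists passing in axenic against conventional, axenic against re-colonized and re-colonized against conventional heads numbered 15, 15 and 1 in experiment 1 (35, 36 and 15 at the preset one) and 1, 1 and 0 in experiment 2 (27, 33 and 19). By fry, the re-colonized against conventional lists numbered 1 in experiment 1 and 0 in experiment 2, and axenic against conventional lists of experiment 2 numbered 16. Without re-colonized 1 and 7, the ribosomal protein list turned downward in axenic against re-colonized heads of experiment 2 (camera adjusted p = 0.975), and the exocrine pancreas list turned upward in re-colonized against conventional heads (camera adjusted p = 0.273), the cause of which was not tested.

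Leaving out 1 library gave 2279 to 3342 axenic against conventional genes, 2586 to 3646 against re-colonized heads, 1690 to 2542 against both, and 0 (without re-colonized F) to 8 (without conventional B) between colonized groups in experiment 1. In experiment 2 it gave 391 (without axenic 7) to 1521 (without conventional 1), 165 (without axenic 7) to 794 (without re-colonized 2), 126 (without axenic 7) to 570 and 0 to 1. Genes called in both experiments numbered 284 and 140 without axenic 7. Whether replicate numbers pair the samples stays open. In experiment 1, same-numbered axenic and conventional, axenic and re-colonized, and colonized libraries correlated at medians of -0.0247, 0.011 and 0.119 (others 0.00998, 0.00666 and -0.00534). In experiment 2 these were 0.128, 0.222 and 0.131 (others 0.00132, -0.0764 and -0.0149). They correlated best with their own number in 1 of 5, 0 of 4 and 2 of 4, and 2 of 4, 2 of 4 and 2 of 7. With the replicate block, re-colonized against conventional genes numbered 6 in experiment 1, where clca1 and si:ch211-69b7.6 did not pass (adjusted p = 0.306 and 0.223), and 2 in experiment 2, and no other count of genes moved by over 1.5 times. With it, sqlea and capn9 of experiment 1 and marco and sc5d of experiment 2 did not pass against re-colonized heads (adjusted p = 0.0669, 0.0665, 0.0603 and 0.0893), nor acp5a of experiment 2 against conventional heads (adjusted p = 0.113).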

Other observations

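The lists of liver X receptor targets and of sterol synthesis enzymes, and the tests on them, were chosen only after the result was seen.

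In axenic against conventional heads of experiment 1, gpnmb, a melanosome glycoprotein, rose by 0.74 (SE 0.11, edgeR adjusted p = 2.67e-05). myh7l, a cardiac myosin heavy chain, rose by 1.57 (SE 0.22, edgeR adjusted p = 1.75e-05). atp5mc1, a subunit of ATP synthase, rose by 1.25 (SE 0.17, edgeR adjusted p = 1.12e-05).

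Enzymes of sterol synthesis rose in 16 of 19 cases against conventional and 17 of 19 against re-colonized heads in experiment 1, and in 9 of 19 against each in experiment 2, and 0 fell. Their score (mean log2 CPM) was 2.84 ± 0.903 in axenic, 1.78 ± 0.0752 in re-colonized and 1.84 ± 0.0856 in conventional heads of experiment 1 (SD, n = 6 each), and axenic pools ranged from 2.04 in axenic G to 4.12 in axenic F. Less sterol sensed in axenic larvae may account for this, as a hypothesis, and targets of liver X receptors, which sense oxidized sterols, would then be lower. Of 8 such targets, 3 fell and 0 rose against re-colonized heads in each experiment, namely abca1a, srebf1 and mylipa, a ligase of the LDL receptor, named after its values were seen. In experiment 2, abca1a did not pass without any 1 of axenic 4 and 7 and re-colonized 3 and 7 (edgeR adjusted p = 0.056 to 0.162), nor with the 2 groups alone (edgeR adjusted p = 0.0706). Their score differed by -0.398 in experiment 1 (4.7 ± 0.165 against 5.1 ± 0.102, SD, n = 6 each, two-sided exact permutation p = 0.00216, the smallest of 924 splits, adjusted p = 0.00648 by Benjamini-Hochberg over 24 tests), lower in 6 of 6 axenic libraries. In experiment 2 it differed by -0.308 (4.75 ± 0.373, SD, n = 4, against 5.06 ± 0.268, SD, n = 7, two-sided exact permutation p = 0.13, adjusted p = 0.164), which does not decide it, but by -0.539 against conventional heads (5.29 ± 0.176, SD, n = 7, two-sided exact permutation p = 0.00909, adjusted p = 0.0156), where 4 of 8 targets fell, and abca1a, srebf1 and 4 other targets also stand in the cholesterol list. Against it, axenic 4 and 7 of experiment 2 (5.07 and 5.08) were not below the re-colonized mean, and among axenic libraries there axenic 7 was highest and axenic 1 lowest in both scores (sterol synthesis 3.17 and 1.45, targets 5.08 and 4.42). Sterols and diet were not measured, and a direct effect of microbes on these genes stays open.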
